A study of Mus musculus with 28 samples.

How the data were processed

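Total RNA of 28 cultures of mouse fibroblasts was hybridised to Affymetrix expression arrays, 1 array per culture. Per the labels' protocols, RNA was extracted with Trizol, purified on RNeasy columns and labelled with a one-cycle biotin kit. RMA, a method that summarises the probes of a probe set after background correction and quantile normalisation, is named per the submitters' processing notes. Its version, and the step at which it was used, are not given in the sources used here.

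The deposited table held log2 values for 45101 probe sets on the 28 arrays. Tested on the file, the linear ratio 2^value had a median of 1 over the 28 arrays, within 0.001, in 45101 of 45101 probe sets. Each deposited log2 value is therefore a log2 ratio to the probe set's own median over all arrays, and the absolute level of a gene has been removed. The lowest value, -6.64, equals a ratio of 0.01 and was held by 4 values, and the highest was 6.37. Signal over background is unknown, so no gene could be called absent and low ratios may lie near background. Array medians were near 0 and array spreads differed. No detection call or scan date was used here.

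Gene symbols came from the platform's annotation table: 34945 probe sets had 1 symbol, 932 had several, 9160 had none and 64 were control probe sets. Of the named probe sets, 34741 matched the RefSeq gene table by Entrez number, and 0 symbols needed an update. Probe sets with several symbols, no symbol or control sequences were left out. The planned rule of keeping each gene's brightest probe set could not be used on values without a level. The probe set with the largest SD over the 28 arrays, taken without the sample labels, replaced it for the 9010 genes with over 1 probe set. That left 18193 genes. A planned filter on dim genes needed the same missing level and was not run. A filter on genes with an SD below the median took its place.

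Groups were taken from the labels, which give cell line, glucose, time and a biological replicate number. No array was moved to another group, although 6 arrays had the profile of the other line. Each of the 14 groups had 2 arrays. limma 3.58.1 in R 4.3.3 was fitted (lmFit and eBayes) with 1 coefficient per group on all 28 arrays, which left 14 residual degrees of freedom. p-values were adjusted by the Benjamini-Hochberg method within each comparison, and an adjusted p under 0.05 with no fold threshold was called. By chance, 910 of 18193 genes would have an unadjusted p under 0.05. Errors given with log2 fold changes are standard errors from limma unless named otherwise.

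A total of 36 gene lists were fixed before the data were examined, 31 of pathways and responses and 5 of markers of leukocytes, epithelial, endothelial, fat and skeletal muscle cells. Of 859 list entries, 809 were measured. Lists were tested with camera at a preset correlation between genes of 0.01, with adjustment over the 36 lists. camera with an estimated correlation and fry were run beside it. The 16 comparisons, the tests, the lists and the rule for named genes were also chosen before the data were examined. That rule named the 8 genes with the largest rise and the 8 with the largest fall among called genes whose arrays did not overlap between groups, up to 4 called members of a list, and a set of genes fixed by name. Clone and predicted-gene symbols were counted and not named. The log2 fold changes of all probe sets of a named gene were compared after the data were seen. Genes named only because they were fixed by name, Txnip and Myc among them, were left out of this comparison. Where the compared log2 fold changes ranged to the opposite sign or to under 25% of the value reported, that end of the range is given.

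Chosen after the data were seen were the averages over time or line, the exact test of glucose and the checks of array identity. The 2 added averages were the line difference at 25 mM over 0, 24, 48 and 72 h and the glucose difference over both lines and 24, 48 and 72 h. The line average was first computed without 0 h, after an array at 0 h was seen out of place. It was replaced by the average over all 4 times, and both are given. For the averages, named genes only had to pass the threshold. The exact test permuted the glucose labels within each line and time, over all 46656 relabelings, and was two-sided. It was run with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1 on the 36 list means and on 14 genes fixed by name. Figures were drawn with matplotlib 3.10.9.

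The fits of 5 comparisons were tested on simulated data for 18193 genes with 200 changed genes, and the others were not. For the line difference at 25 mM and 72 h, 33% of changes of 1 log2 unit and 77% of changes of 2 units were recovered, with 5 false calls of 115. For 72 against 0 h in NIH3T3, 33% and 69% were recovered, with 6 false calls of 108, and for glucose in NIH3T3 at 72 h, 33% and 76%, with 8 of 117. The average over times recovered 72% and 96% for the lines, with 2 false calls of 170, and that over lines and times 90% and 94% for glucose, with 14 of 198. A shifted list was called in each of these simulations, and 0 of the other lists were. The simulated genes varied independently of each other. Neither the list calls nor the false calls were therefore tested under correlation between genes. On the data, 79 of 80 list calls were lost with an estimated correlation. The exact test called 6.0% of simulated lists without a shift and 100.0% with a shift of 1 log2 unit.

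Alternatives were another quantile normalisation, centring of each array, the mean of a gene's probe sets, probe sets ending in _x_at or _s_at left out, a mean-variance trend with robust variance, only the compared arrays, the replicate number as a block, a log2 fold change of at least 1, and each array left out. Added after the data were seen were the fit without the 6 arrays out of place, the SD filter and a block for the level of the bioC hybridisation control. The number of arrays limits the precision of every value.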

Results

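Gene expression was measured in NIH3T3, an immortalised mouse embryonic fibroblast line, and in a line labelled NIH3T3 K-ras, shortened to K-ras below, also in array labels. Cells were collected at the medium change (0 h, at 25 mM glucose) and after a further 24, 48 and 72 h at 25 mM or 1 mM glucose. The 14 groups of line, glucose and time held 2 arrays each, labelled as biological replicates. The study asked which genes respond to glucose availability in the 2 lines. All values are log2 ratios to a gene's median over the 28 arrays, so differences between groups can be read and levels between genes cannot.

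The arrays fell into 2 clusters of 14 on the 500 genes with the largest SD, and the clusters differed in genes such as Il33, an alarmin cytokine, and Krt14, a basal epithelial keratin. Il33 lay between -6.52 and -5.52 in 11 of the 14 arrays labelled NIH3T3 and between 1.26 and 3.11 in 11 of the 14 labelled K-ras. Krt14 lay between 0.95 and 2.49 in the former and between -4.58 and -3.90 in the latter. The other 6 arrays lay with the opposite line. These were both arrays labelled NIH3T3 1 mM 24 h, replicate 1 of NIH3T3 1 mM 48 h, and replicate 1 of K-ras 25 mM 0 h, K-ras 1 mM 48 h and K-ras 1 mM 72 h. Both arrays were in place in 9 of the 14 groups. The labels were kept for every test. In the 4 groups with 1 such array, profiles of both lines are mixed, which widens the spread that all comparisons share. In NIH3T3 1 mM 24 h both arrays had the profile of the other line, so glucose and line cannot be told apart in its comparison with 25 mM. The correlation between replicates over all 18193 genes had a median of 0.27 and ranged from -0.53 to 0.88, and 6 of 28 arrays correlated best with their own replicate.

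**Figure D1:**
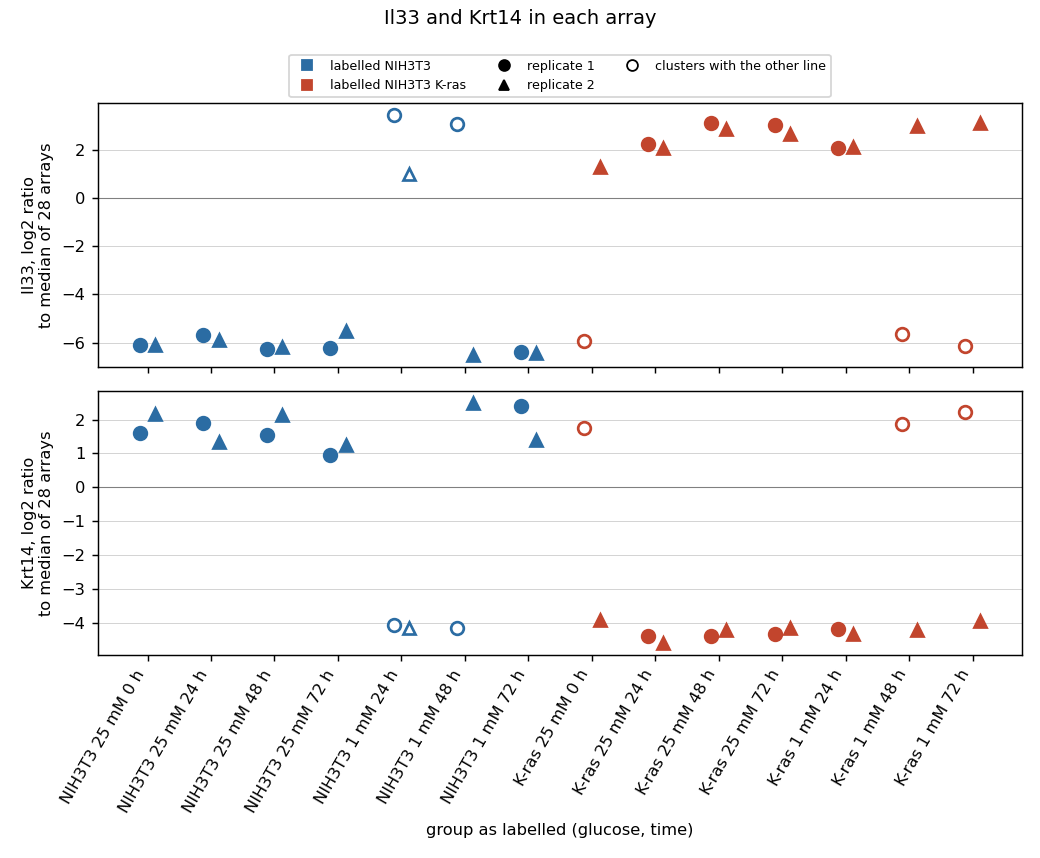
Log2 ratio of Il33 (top) and Krt14 (bottom) to the median of 28 arrays, for each array by labelled group, with circles for replicate 1 and triangles for replicate 2. The 6 open symbols are arrays that cluster with the other line, such as those labelled NIH3T3 with Il33 between 0.98 and 3.42 and those labelled K-ras with Il33 between -6.14 and -5.64.

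The hybridisation control bioC, RNA added in a fixed amount to each sample, split the arrays in another way. It was low, between -2.34 and -0.84, on 12 arrays, all labelled NIH3T3, and at least -0.26 on the other 16. The labels name no batch, and bioC batch here means only this split, cut at -0.6 after the values were seen. The companion control bioB overlapped, from -1.20 to 0.22 on the low arrays and from -0.69 to 3.07 on the others. Every NIH3T3 array at 25 mM was low in bioC and every K-ras array at 25 mM was high, so at 25 mM this split and the line coincide. All arrays compared over time within NIH3T3, and all K-ras arrays, lay within a single bioC batch. A block for bioC could be estimated only from the NIH3T3 groups at 1 mM and 48 h or 72 h, which held both levels. In the 48 h group the array with high bioC had the profile of the K-ras line. Fits with this block therefore also remove part of the line difference and cannot separate line from bioC.

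At 25 mM and 72 h, K-ras arrays held more mRNA of growth factor signalling genes than NIH3T3 arrays. Here and in all line comparisons a single line of each kind was measured, not independent transformants, so a difference cannot be credited to K-ras itself. Fosl1, an AP-1 transcription factor induced by ERK signalling, differed most among the named genes higher in K-ras arrays (log2 fold change 4.99 ± 0.57, adjusted p = 0.00105), at 0.34 ± 0.06 (SD, n = 2) against -4.64 ± 0.20 (SD, n = 2). Dusp4, a phosphatase of MAP kinases (3.76 ± 0.70), Ereg, an EGF receptor ligand (3.32 ± 0.69), and Phlda1 (3.22 ± 0.61) were also higher. In NIH3T3 alone, Fosl1 had a log2 fold change of -4.43 from 0 to 72 h, so the gap at 72 h includes a fall in that line. In the list of RAS-MAPK output genes, 6 of 25 were higher and 0 lower, or 14 and 0 adjusted over the list alone. The median log2 fold change of the list was 1.30 (camera adjusted p = 1.06e-07). The call was lost at adjusted p = 0.347 with an estimated correlation. Other genes higher in K-ras arrays were Dio2, which activates thyroid hormone (4.13 ± 0.64), the matrix proteins Sparcl1 (4.11 ± 0.83) and Lum (3.86 ± 0.75), Prkcb (3.52 ± 0.66) and Noct (3.50 ± 0.53). Lower in K-ras arrays were Srpx2 (-5.49 ± 1.22), Ranbp3l (-4.40 ± 0.34, adjusted p = 5.02e-06), the cytokine signalling inhibitor Socs2 (-4.20 ± 0.90), Zbtb20 (-4.19 ± 0.89), Aff3 (-3.59 ± 0.70), Hoxa2 (-3.49 ± 0.77), Cped1 (-3.45 ± 0.74) and the platelet isoform of phosphofructokinase, Pfkp (-3.75 ± 0.82). Bid, a pro-apoptotic BCL2 family member (-1.88 ± 0.41), and Tef, a circadian output factor (-1.54 ± 0.32), were lower too. Another probe set of the gene stood at -0.05 for Dio2, 0.24 for Prkcb, 0.15 for Socs2, -0.30 for Pfkp, -0.06 for Aff3 and -0.42 for Bid.

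The autophagy and lysosome list lay lower in K-ras arrays at 72 h, with a median of -0.55, 3 of 34 members positive and 7 lower adjusted over the list alone (camera adjusted p = 5.26e-05, and adjusted p = 0.646 with an estimated correlation), and a median of -0.83 without replicate 2 of K-ras. The DNA replication list had a median of 0.94 with 38 of 41 members positive (camera adjusted p = 0.00051, and adjusted p = 0.791 with an estimated correlation), and one of -0.10 with the bioC batch as a block. It was 1.49 without replicate 1 of K-ras and 0.55 without replicate 2, and the latter ended the call (camera adjusted p = 0.514). Replicate 1 of K-ras stood apart from all other arrays, with bioC at 2.98 against 0.83 for the next and an interquartile range of 0.65 against 0.45. None of the members of these 2 lists passed over all genes. In all, limma called 132 genes, 56 higher and 76 lower, against 3929 at an unadjusted p under 0.05. The count depended on single arrays: it was 3014 without replicate 2 of K-ras 25 mM 72 h and 2 without any 1 of the other 3 arrays compared. Normalised again by quantiles, it was 5, of which 4 were higher, and with the bioC batch as a block it was 1.

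At 0 h, Acta1, the skeletal muscle actin (-4.19 ± 0.62, adjusted p = 0.0324), and the atrial myosin light chain Myl7 (-1.47 ± 0.20, adjusted p = 0.0257) were lower in K-ras arrays. These were the 2 genes called by limma, and 851 had an unadjusted p under 0.05. Of the 4 arrays, K-ras 25 mM 0 h replicate 1 had the profile of the other line. The count was 0 without either K-ras array or without NIH3T3 replicate 2, and 410 without the 6 arrays out of place. The limma counts were 12 genes at 24 h (11 higher, 1 lower) and 3 at 48 h. The latter, named after their values were seen, were Dio2 (4.24 ± 0.64) and Lrrc17 (2.54 ± 0.40), higher in K-ras arrays, and Ranbp3l (-2.18 ± 0.34), lower, with another probe set at 0.29, -0.10 and -0.50. At 24 h the count was 20 and 37 without replicates 1 and 2 of NIH3T3 and 0 without either K-ras array. At 48 h it was 12 without replicate 2 of K-ras and 0 without replicate 1 of either line. After quantile normalisation 0 and 1 genes were called, the latter lower. With only the compared arrays fitted, the counts at 24 h and 48 h were 1028 and 276, and both also rose without the 6 arrays out of place.

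Averaged over the 4 times at 25 mM, a comparison added after the data were seen, the lines differed in 2064 genes, 1032 in each direction. Of these, 828 had an absolute log2 fold change of at least 1. The arrays included K-ras 25 mM 0 h replicate 1, which had the profile of the other line, and the count rose without the 6 arrays out of place. Crabp1, which binds retinoic acid (7.71 ± 1.39, adjusted p = 0.00492), Il33 (7.40 ± 1.51, adjusted p = 0.00667), Cytip (5.51 ± 1.02), Ngef (5.41 ± 0.97), Ccbe1 (4.73 ± 0.92), Defb41 (4.54 ± 0.84), Tcim (4.29 ± 0.70) and the semaphorin Sema7a (4.12 ± 0.66) were highest in K-ras arrays. Lowest were Anxa8 (-5.19 ± 0.94), Krt14 (-5.13 ± 1.07), Slurp1 (-4.76 ± 1.02), the cathepsin inhibitors Ctla2a (-4.44 ± 0.95) and Ctla2b (-3.99 ± 0.85), the retinaldehyde dehydrogenase Aldh1a1 (-4.38 ± 0.81), Sulf1 (-4.07 ± 0.89) and Mustn1 (-3.84 ± 0.63). Another probe set of the gene stood at 0.09 for Ccbe1, 0.58 for Sema7a, -0.17 for Krt14 and 0.00 for Sulf1. The count was 961 without replicate 2 of K-ras 25 mM 0 h, 1308 and 1298 without replicate 2 of NIH3T3 25 mM at 0 h and 72 h, and 1372 and 1366 without replicate 2 of K-ras 25 mM at 24 h and 48 h. The other 11 fits without an array gave 1416 to 2823. With the bioC batch as a block, which coincides with the line at 25 mM, it was 0.

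Several gene groups went with this line difference. Of the RAS-MAPK output genes, 10 of 25 were higher and 1 lower, or 17 and 1 adjusted over the list alone, with Fosl1 at 2.13 ± 0.29, Ereg at 1.71 ± 0.34, the feedback inhibitor Spry4 at 1.68 ± 0.36 (0.11 by another probe set) and Dusp4 at 1.67 ± 0.35. The list's median was 0.87 (camera adjusted p = 6.91e-09), with adjusted p = 0.225 with an estimated correlation and adjusted p = 0.00208 in fry. Cholesterol synthesis genes were higher in 5 of 20 cases and lower in 0, or 7 and 0 adjusted over the list alone, led by Lss (1.72 ± 0.30) and Tm7sf2 (1.50 ± 0.42), enzymes of the sterol ring steps (camera adjusted p = 2.73e-05, and adjusted p = 0.913 with an estimated correlation). Cytokine and inflammatory genes were higher in 7 and lower in 1 of 25, or 10 and 2 adjusted over the list alone, with the chemokine Ccl2 at 1.97 ± 0.61, the prostaglandin synthase Ptges at 1.74 ± 0.32 and Ccl9 at -1.57 ± 0.39 (camera adjusted p = 0.00171, and adjusted p = 0.913 with an estimated correlation). The TCA cycle list (5 higher and 2 lower of 23, or 9 and 2 adjusted over the list alone) had camera adjusted p = 0.0131, and the DNA replication list (2 and 0 of 41, or 0 and 0 adjusted over the list alone) 0.0162. Both had adjusted p = 0.913 with an estimated correlation. The TCA cycle call was lost without replicate 2 of K-ras 25 mM 72 h (median 0.13, camera adjusted p = 0.124). The DNA replication call was lost without that array (0.20, camera adjusted p = 0.348), NIH3T3 25 mM 48 h replicate 1 (0.024, 0.573), K-ras 25 mM 0 h replicate 1 (0.25, 0.171) or K-ras 25 mM 48 h replicate 2 (0.26, 0.0792), and its median was 0.59 without NIH3T3 25 mM 48 h replicate 2. With the bioC batch as a block, the DNA replication list had a median of -0.82, Fosl1 stood at 0.87 and Ereg at -0.29, neither gene called. Because the block also takes up line difference, these values do not test the batch.

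Other groups moved in both directions between the lines. Among collagens and fibrous matrix genes, 4 were higher and 7 lower of 35, or 5 and 9 adjusted over the list alone, with Thbs2 at 3.93 ± 0.70, Lum at 2.53 ± 0.38, Mfap5 at -2.56 ± 0.57 and Col11a1 at -2.36 ± 0.70. Of the p53 targets, 1 was higher and 4 lower of 19, with the same counts adjusted over the list alone, including the BH3-only genes Pmaip1 (-1.42 ± 0.42) and Bbc3 (-0.92 ± 0.25). Of the interferon response genes, 1 was higher and 4 lower of 37, or 1 and 5 adjusted over the list alone, with Ifit3 at -1.20 ± 0.19. In glycolysis, Eno2 (2.67 ± 0.69) and Pdk1 (1.70 ± 0.45) were higher and Pfkp (-2.37 ± 0.41, or -0.23 by another probe set) and Pfkfb4 (-0.93 ± 0.29) lower, of 23 genes. Adjusted over the list alone, 7 were higher and 4 lower. The camera adjusted p of these 4 lists lay at 0.796, 0.296, 0.279 and 0.317. With the bioC batch as a block, Col11a1 stood at 0.84, Bbc3 at 0.15 and the collagen list's median at 0.25. Adm, a vasodilator peptide induced by low oxygen (-3.26 ± 0.55), the metalloprotease inhibitor Timp3 (-2.36 ± 0.46) and Arrdc4, a glucose-responsive arrestin (-1.20 ± 0.27, adjusted p = 0.0101), were lower. The marker lists gave 1 higher and 1 lower of 14 for leukocytes, 0 and 3 of 12 for epithelial cells, 2 and 0 of 10 for endothelial cells, 1 and 1 of 9 for fat cells and 0 and 2 of 12 for skeletal muscle, with camera adjusted p between 0.431 and 0.992.

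Over time at 25 mM in NIH3T3, 72 h was compared with 0 h. The 4 arrays of this comparison were all in place and of a single bioC batch. limma called 1004 genes, 670 higher and 334 lower. The count was 20, 67, 58 and 180 when replicates 1 and 2 at 72 h and replicates 2 and 1 at 0 h were left out in turn. After quantile normalisation it was 615, of which 341 were higher and 274 lower. The genes that rose most were Scara5 (5.20 ± 1.17), the matrix proteoglycans Prelp (5.07 ± 1.37) and Ogn (4.60 ± 1.02), the p53 target Trp53inp1 (4.85 ± 0.87), Klhl24 (4.63 ± 0.94), Ranbp3l (4.48 ± 0.34, adjusted p = 3.69e-06), Ccng2, a cyclin of resting cells (4.34 ± 0.96), and the noncoding RNA Neat1 (4.28 ± 1.06). Another probe set of the gene stood at -0.01 for Scara5, 0.64 for Trp53inp1, 1.02 for Klhl24 and 0.18 for Neat1. The genes that fell most were the actins Actg2 (-5.04 ± 0.76) and Acta1 (-4.84 ± 0.62), the growth factor Hbegf (-4.52 ± 0.92), Fosl1 (-4.43 ± 0.57, adjusted p = 0.00135), Serpinb2 (-4.38 ± 1.06), Tubb3 (-4.06 ± 0.93), Tagln (-4.05 ± 0.65) and Pmepa1 (-3.65 ± 0.51).

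Of 30 genes of the nucleolus and ribosome biogenesis list, 19 fell and 0 rose, or 26 and 0 adjusted over the list alone. Among them were the nucleolar protein Nolc1 (-2.69 ± 0.53), Nhp2 (-2.47 ± 0.61), Nop16 (-2.37 ± 0.48) and Rrp12 (-2.35 ± 0.49). The list's median was -1.51 (camera adjusted p = 2.75e-21, fry adjusted p = 0.000564), with adjusted p = 0.0945 with an estimated correlation. Nucleotide synthesis genes fell in 6 of 23 cases and rose in 1, or 11 and 1 adjusted over the list alone, with the purine enzymes Ppat (-2.61 ± 0.52, or -0.47 by another probe set), Gart (-1.80 ± 0.38) and Pfas (-1.69 ± 0.27) lower (camera adjusted p = 1.42e-07, and adjusted p = 0.118 with an estimated correlation). Of the cytosolic tRNA synthetases, 5 of 19 fell and 0 rose, or 13 fell and 1 rose adjusted over the list alone, with Farsb at -1.58 ± 0.41 and Cars at -1.27 ± 0.25 (camera adjusted p = 1.69e-07, and adjusted p = 0.0945 with an estimated correlation). The DNA replication list had a median of -1.81 with 0 of 41 members positive and 22 lower adjusted over the list alone, of which Mcm3 (-3.09 ± 0.88, or -0.67 by another probe set) and Cdt1 (-2.42 ± 0.64, or -0.15) passed over all genes (camera adjusted p = 2.11e-13, and adjusted p = 0.345 with an estimated correlation). The mitosis list had a median of -1.73 with 0 of 39 members positive and 0 called by limma (camera adjusted p = 1.42e-07, and adjusted p = 0.519 with an estimated correlation).

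Of the RAS-MAPK output genes, 7 of 25 fell and 0 rose, or 10 and 0 adjusted over the list alone, including Hbegf, Fosl1, Ereg (-3.54 ± 0.69) and Dusp5 (-3.11 ± 0.44) (camera adjusted p = 1.2e-06, and adjusted p = 0.118 with an estimated correlation). Contractile and YAP-SRF genes fell in 4 of 20 cases and rose in 0, or 6 and 0 adjusted over the list alone, with the secreted YAP target Ccn1 at -3.37 ± 0.90 and smooth muscle actin Acta2 at -1.83 ± 0.47, or -0.21 by another probe set (camera adjusted p = 4.72e-05, and adjusted p = 0.214 with an estimated correlation). The marker list of skeletal muscle cells, to which Acta1 belongs, had a median of -0.17 with 1 of 12 lower, also adjusted over the list alone (camera adjusted p = 0.148), and scores of 0.45 and 0.59 at 0 h and 0.03 and -0.04 at 72 h. The lists of macrophages and leukocytes, epithelial cells, endothelial cells and adipocytes had camera adjusted p between 0.814 and 0.882. Timp1 (-3.37 ± 0.62), the urokinase receptor Plaur (-2.68 ± 0.55) and the cyclooxygenase Ptgs2 (-2.92 ± 0.68) also fell, and so did the serine and folate enzymes Mthfd2 (-2.25 ± 0.52) and Shmt2 (-2.09 ± 0.36).

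Growth arrest and FOXO target genes rose in 8 of 25 cases and fell in 0, or 10 and 1 adjusted over the list alone, with the PDGF receptor Pdgfra (3.73 ± 0.80), Gas1 (3.54 ± 0.63) and Pik3ip1 (3.25 ± 0.61) (camera adjusted p = 9.63e-06, and adjusted p = 0.0945 with an estimated correlation). Autophagy and lysosome genes rose in 7 of 34 cases and fell in 0, or 13 and 0 adjusted over the list alone. The lysosomal proteases Tpp1 (2.31 ± 0.53) and Ctsd (1.55 ± 0.37) were among them (camera adjusted p = 6.47e-09, and adjusted p = 0.118 with an estimated correlation). Fatty acid oxidation genes rose in 5 of 22 cases and fell in 0, or 12 and 0 adjusted over the list alone, with the pyruvate dehydrogenase kinase Pdk4 (2.02 ± 0.54) and Acadm (1.59 ± 0.38) (camera adjusted p = 1.01e-08, and adjusted p = 0.118 with an estimated correlation). Cholesterol synthesis genes rose in 3 of 20 cases and fell in 0, or 6 and 0 adjusted over the list alone, with Mvd at 1.85 ± 0.46 and Insig1 at 1.51 ± 0.26 (camera adjusted p = 3.94e-07, and adjusted p = 0.182 with an estimated correlation). Interferon response genes rose in 4 of 37 cases and fell in 0, or 10 and 0 adjusted over the list alone, with the RNA sensor Ddx58 (2.38 ± 0.52, or 0.03 by another probe set) and Ifitm3 (2.17 ± 0.47) (camera adjusted p = 6.07e-05, and adjusted p = 0.142 with an estimated correlation). The hexosamine genes Nagk (1.86 ± 0.45) and Amdhd2 (1.81 ± 0.45) rose. The glycolysis list had a median of -0.07 (camera adjusted p = 0.966), in which Ldhb (2.08 ± 0.45) and Pfkm (1.05 ± 0.21) rose and the lactate transporter Slc16a1 (-1.46 ± 0.30) fell.

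**Figure D2:**
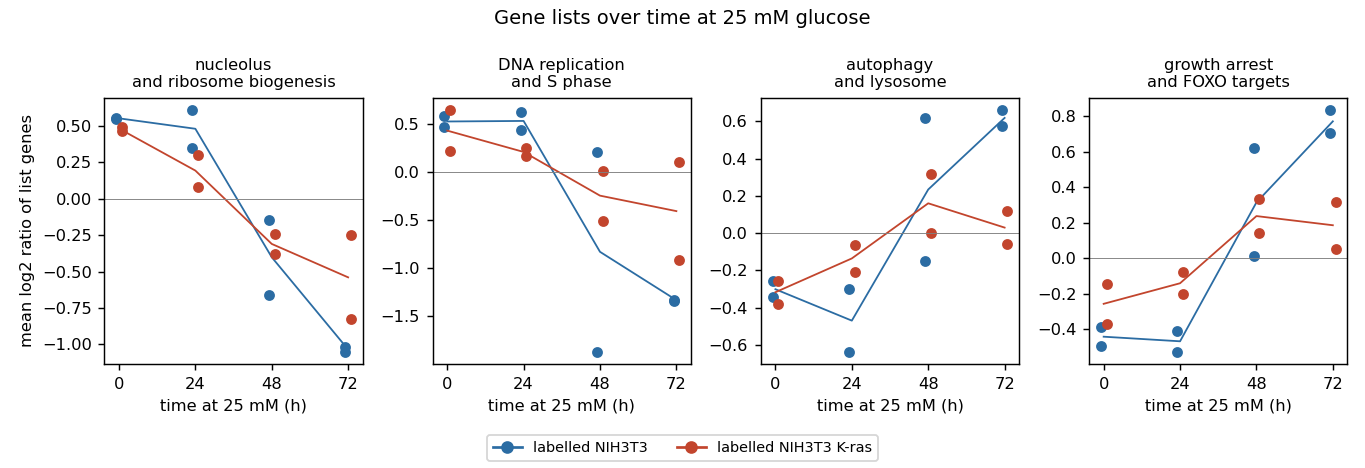
Mean log2 ratio of the genes of 4 fixed lists against time at 25 mM glucose, with 1 point per array and lines through the means of 2 arrays, in arrays labelled NIH3T3 (blue) and K-ras (red). In NIH3T3 the list nucleolus and ribosome biogenesis stood at 0.55 and 0.54 at 0 h and at -1.05 and -1.02 at 72 h.

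In the K-ras line, the nucleolus and ribosome biogenesis list was lower at 72 h than at 0 h, with a median of -0.90, 0 of 30 members positive and 18 lower adjusted over the list alone (camera adjusted p = 3.49e-15, and adjusted p = 0.213 with an estimated correlation). The DNA replication list had a median of -0.87 with 0 of 41 members positive (camera adjusted p = 1.75e-05, and adjusted p = 0.629 with an estimated correlation), and one of -0.30 without replicate 1 at 72 h. The cholesterol list had a median of 0.77 with 16 of 20 positive and 5 higher adjusted over the list alone (camera adjusted p = 0.000195, and adjusted p = 0.553 with an estimated correlation). The adipocyte marker list had a median of 0.35 with 3 of 9 higher adjusted over the list alone (camera adjusted p = 0.0308, and adjusted p = 0.543 with an estimated correlation). It was -0.02 without replicate 1 at 72 h (camera adjusted p = 0.528), 0.63 without replicate 2 at 72 h, and not called without replicate 2 at 0 h (camera adjusted p = 0.111). The p53 target list had a median of -0.71, 3 of 19 positive and 2 lower adjusted over the list alone (camera adjusted p = 0.000217, and adjusted p = 0.158 with an estimated correlation), and a median of -0.44 without replicate 1 at 72 h. That array stood apart in its hybridisation controls, with bioC at 2.98 against 0.83 for the next highest array, and in its interquartile range, 0.65 against 0.45. limma called 0 genes, with 2791 at an unadjusted p under 0.05. Of the 4 arrays, K-ras 25 mM 0 h replicate 1 was out of place. The count was 2552 without replicate 2 at 72 h and 0 without any other 1 of the 4. Whether the time course differed between the lines was not tested.

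Low glucose was compared with high glucose in each line and at each time. The arrays of each line at 25 mM and 72 h also served in the line comparison at 72 h and in the comparison over time. Results of these comparisons are therefore not independent. In NIH3T3, Ranbp3l and the nucleolus and ribosome biogenesis list moved in opposite directions over time and with low glucose. A state particular to the shared arrays would give such opposite shifts, and this was not tested. In NIH3T3 at 72 h, Ranbp3l (-2.66 ± 0.34, adjusted p = 0.00757), at 1.80 ± 0.06 (SD, n = 2) against 4.47 ± 0.07 (SD, n = 2), and Klhl9 (-1.03 ± 0.16, adjusted p = 0.0411) fell. These were the only 2 genes called, with 1224 at an unadjusted p under 0.05. The nucleolus and ribosome biogenesis list was higher at 1 mM, with a median of 0.75, 29 of 30 members positive and 9 higher adjusted over the list alone (camera adjusted p = 6.9e-13, and adjusted p = 0.276 with an estimated correlation). The tRNA synthetase list was higher too, with a median of 0.81, 18 of 19 positive and 9 higher adjusted over the list alone (camera adjusted p = 8.71e-12). It was the only list called with an estimated correlation in the 9 comparisons whose lists were tested, at adjusted p = 0.0427, and fry gave adjusted p = 0.00774. The ATF4 and amino acid response list had a median of 0.72 with 2 higher adjusted over the list alone (camera adjusted p = 6.5e-06, and adjusted p = 0.575 with an estimated correlation). Its median was 1.38 without replicate 1 at 1 mM and 0.12 without replicate 2, and the latter ended the call (camera adjusted p = 0.979). The RAS-MAPK list had a median of 0.77 with 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.71e-05, and adjusted p = 0.276 with an estimated correlation). The other called lists had negative medians. These were growth arrest and FOXO targets (-0.59), fatty acid synthesis (-0.28) and oxidation (-0.27), autophagy and lysosome (-0.21) and cholesterol synthesis (-0.19). Respiratory complexes III, IV and V (-0.15), complex I (-0.12) and interferon response (-0.09) were the rest. Their camera adjusted p ran from 0.0009 to 0.0325, and each call was lost when 1 array or another was left out. The glycolysis list had a median of 0.00 (camera adjusted p = 0.57). Txnip stood at a log2 fold change of -3.46 ± 1.08 (adjusted p = 0.5) and was not called. The count of genes was 0 without either array at 25 mM, 1 without replicate 2 at 1 mM, 0 after quantile normalisation and 8 without the 6 arrays out of place, none of which belong to this comparison. With the bioC batch as a block it was 0.

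In the K-ras line at 72 h, cholesterol synthesis genes were lower at 1 mM. The regulator Srebf2 (-1.63 ± 0.31) and the enzyme Fdps (-1.59 ± 0.25) fell, 12 of 20 members were lower adjusted over the list alone, and 0 of 20 were positive. The median was -1.02 (camera adjusted p = 5.23e-10, and adjusted p = 0.663 with an estimated correlation), and -1.82 and -0.53 without replicates 1 and 2 at 1 mM. The adipocyte marker list was lower too, with a median of -0.31 and 2 of 9 lower adjusted over the list alone (camera adjusted p = 0.0476, and adjusted p = 0.663 with an estimated correlation). It lost its call without replicate 1 at 25 mM (0.02, camera adjusted p = 0.47) or replicate 1 (-0.18, 0.166) or 2 (-0.32, 0.0749) at 1 mM. The genes that rose were Tmem47 (2.92 ± 0.51), Larp1b (2.70 ± 0.52), Strn (1.67 ± 0.28), Tent4b (1.48 ± 0.28), Ngdn (1.35 ± 0.26) and Wapl (1.21 ± 0.23). Those that fell most were Gas7 (-4.44 ± 0.81), the actin crosslinker Actn1 (-3.13 ± 0.60), the retinoic acid receptor Rarg (-2.59 ± 0.36, adjusted p = 0.0285), Cyb5r3 (-2.50 ± 0.41), Errfi1, a feedback inhibitor of the EGF receptor (-2.24 ± 0.43), Fgd4 (-2.22 ± 0.41), Lrrc17 (-2.11 ± 0.40) and Triobp (-1.99 ± 0.31). The succinate dehydrogenase subunit Sdhc fell as well (-1.20 ± 0.18). Another probe set turned direction for Larp1b (-0.11), Strn (-0.27), Gas7 (0.30), Fgd4 (0.29), Lrrc17 (0.04) and Fdps (0.06), and stood at 0.04 for Wapl, -0.33 for Actn1 and -0.20 for Cyb5r3. limma called 33 genes, 6 higher and 27 lower, with 2791 at an unadjusted p under 0.05. The 1 mM group held an array out of place, K-ras 1 mM 72 h replicate 1, which also had the highest Gapdh 3' minus 5' difference of all arrays, 2.09 against 0.43 for the next. The count was 138 without it, 86 without replicate 2 at 1 mM, 0 and 2517 without replicates 1 and 2 at 25 mM, and 0 after quantile normalisation. Replicate 1 at 25 mM, the only 25 mM array behind the count of 2517, stood apart as well, with bioC at 2.98 and an interquartile range of 0.65.

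Further lists in the K-ras line at 72 h were higher or lower at 1 mM, and each of the 5 calls that follow was lost without a single array. The ATF4 and amino acid response list had a median of 1.00 with 5 higher and 1 lower of 32 adjusted over the list alone (camera adjusted p = 0.000229, and adjusted p = 0.8 with an estimated correlation). It had a median of 0.51 without replicate 2 at 1 mM (camera adjusted p = 0.755) and lost its call without replicate 2 at 25 mM (camera adjusted p = 0.224). The ER chaperone and unfolded protein response list had a median of 0.95 with 25 of 27 positive and 1 higher adjusted over the list alone (camera adjusted p = 0.000201, and adjusted p = 0.755 with an estimated correlation). Without replicates 1 and 2 at 1 mM, this median was 1.80 and -0.01, the latter not called (camera adjusted p = 0.875). The collagen list had a median of -0.98 with 1 lower adjusted over the list alone (camera adjusted p = 0.000229, and adjusted p = 0.663 with an estimated correlation). Without replicate 2 at 1 mM it was -0.29 (camera adjusted p = 0.544), and without replicate 1 at 25 mM -0.50. The cytokine list had 7 of 25 members positive and 8 lower adjusted over the list alone (camera adjusted p = 0.00144, and adjusted p = 0.663 with an estimated correlation), and no call without replicate 2 at 25 mM (camera adjusted p = 0.123). The mitosis list had a median of -0.92 with 0 called adjusted over the list alone (camera adjusted p = 0.00376, and adjusted p = 0.8 with an estimated correlation). It was -2.06 and 0.10 without replicates 1 and 2 at 1 mM, the latter not called (camera adjusted p = 0.919), and -0.49 without replicate 2 at 25 mM (camera adjusted p = 0.569).

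At 24 h in NIH3T3, the cell cycle transcription factor E2f5 was higher at 1 mM (2.40 ± 0.33, adjusted p = 0.0239), at 0.68 ± 0.12 (SD, n = 2) against -1.72 ± 0.35 (SD, n = 2), while another of its 3 probe sets stood at -0.51. It was the gene limma called there, named after its values were seen, and 0 genes were called at 48 h and in K-ras at 24 h and 48 h. The counts at an unadjusted p under 0.05 were 2933 and 248 in NIH3T3 and 117 and 759 in K-ras. Both NIH3T3 arrays at 1 mM and 24 h were out of place, so a glucose difference there, that of E2f5 included, cannot be told from a line difference. The 48 h comparisons held 1 array out of place each. The count in NIH3T3 at 24 h was 19, 14, 0 and 9 when replicates 1 and 2 at 25 mM and replicates 1 and 2 at 1 mM were left out in turn. At 48 h it was 2 without NIH3T3 25 mM replicate 2 and 1 without NIH3T3 1 mM replicate 2, and in K-ras 7 without 25 mM replicate 2 and 1 without 1 mM replicate 2.

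Averaged over both lines and the 3 later times, a comparison added after the data were seen, low glucose went with less Txnip and more Myc. Txnip, the thioredoxin-interacting protein induced by glucose, was lower at 1 mM in 6 of 6 pairs of groups, by a mean log2 difference of -1.96 (exact permutation p = 0.00133, adjusted p = 0.0186 over the 14 genes tested). In NIH3T3 at 72 h it stood at 3.51 and 3.50 at 25 mM and at 1.31 and -1.22 at 1 mM. Myc, the growth-promoting transcription factor, was higher at 1 mM in 5 of 6 pairs, by 0.90 (exact permutation p = 0.00347, adjusted p = 0.0243). Without the 6 arrays out of place, which leaves no 1 mM array for NIH3T3 at 24 h and so 5 pairs with fewer relabelings, the differences over these 5 pairs were -2.06 for Txnip and 1.00 for Myc, both with an adjusted exact permutation p of 0.0792. Over 29 alternatives they ranged from -2.17 to -1.60 and from 0.73 to 1.07. Txnip had an adjusted p of 0.0504 without NIH3T3 25 mM 48 h replicate 2. Myc lost its call without 6 of 24 arrays, NIH3T3 25 mM 24 h replicate 2 (adjusted p = 0.0591), NIH3T3 25 mM 48 h replicate 2 (0.0504), NIH3T3 25 mM 72 h replicates 1 (0.072) and 2 (0.0645), K-ras 25 mM 72 h replicate 1 (0.127) and K-ras 1 mM 72 h replicate 2 (0.0945). In limma over all genes the adjusted p of Txnip was 0.695 and that of Myc 0.908.

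The other genes fixed by name were not called in this exact permutation test. Ddit3 (mean log2 difference 1.15, higher in 6 of 6 pairs), Trib3 (1.00, 5 of 6), Asns (0.28, 3 of 6) and Arrdc4 (-0.54, 3 of 6) each had an adjusted p of 0.25. Hspa5 (0.58), Hk2 (0.37) and Cdkn1a (0.26) had an adjusted p of 0.308, Slc2a1 (0.19) and Mki67 (-0.32) of 0.588, Ccnd1 (-0.13) of 0.886, Gfpt1 (0.03) of 0.945 and Ldha (-0.00) of 0.971. No list passed over the 36 lists. The lowest exact p were those of fatty acid synthesis (-0.26, p = 0.00806), interferon response (-0.14, p = 0.0144), cholesterol synthesis (-0.39, p = 0.0163) and tRNA synthetases (0.23, higher in 6 of 6 pairs, p = 0.0182), each with adjusted p = 0.164. The ATF4 and amino acid response list was higher in 6 of 6 pairs by 0.47 (exact permutation p = 0.0514, adjusted p = 0.24).

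**Figure D3:**
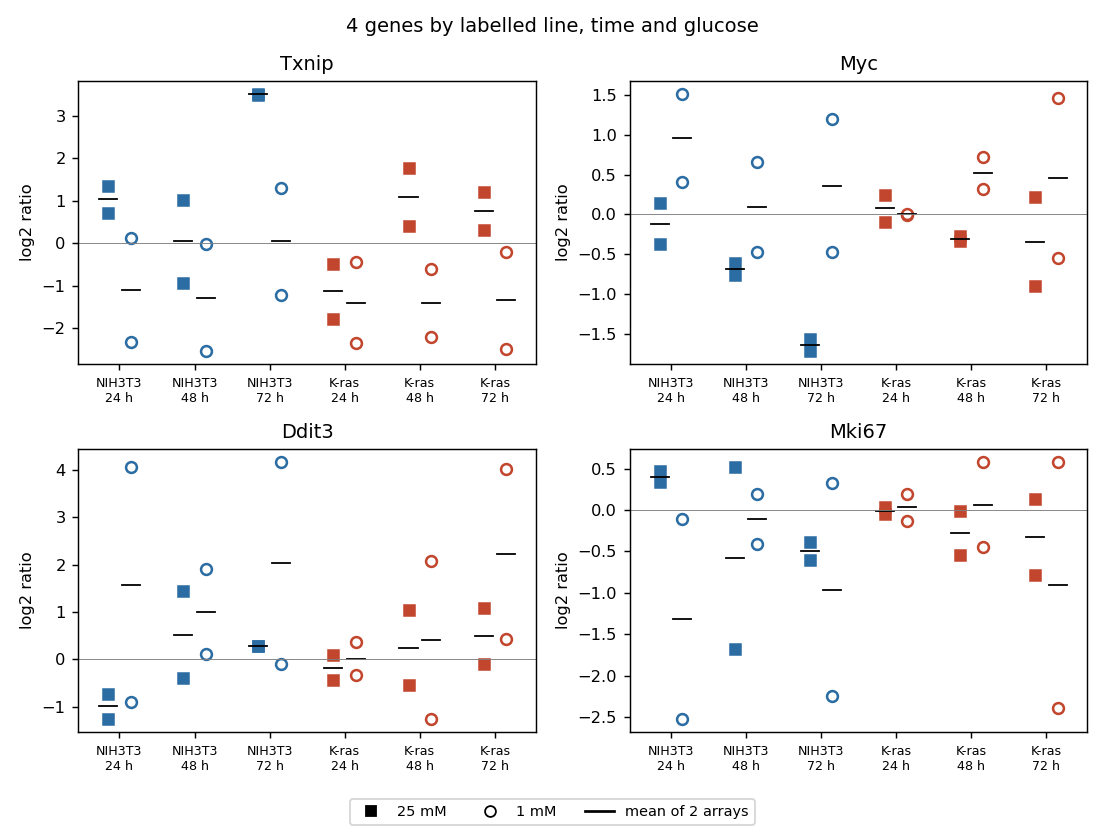
Log2 ratio of Txnip, Myc, Ddit3 and Mki67 in each array at 24, 48 and 72 h by labelled line, with filled squares for 25 mM, open circles for 1 mM and bars for the mean of 2 arrays. Ddit3 stood at 4.05, 4.17 and 4.01 in 3 arrays at 1 mM, in which Mki67 stood at -2.52, -2.25 and -2.39.

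camera on the averaged glucose difference called 17 of 36 lists, and 0 with an estimated correlation. The cholesterol list had a median of -0.38 with 0 of 20 members positive and 2 lower adjusted over the list alone (camera adjusted p = 4.16e-13, and adjusted p = 0.112 with an estimated correlation). The ATF4 list had one of 0.43 with 29 of 32 positive and 0 called adjusted over the list alone (camera adjusted p = 9.91e-13, and adjusted p = 0.205 with an estimated correlation). The tRNA synthetase list had one of 0.28 with 17 of 19 positive and 3 higher adjusted over the list alone (camera adjusted p = 9.94e-10, and adjusted p = 0.101 with an estimated correlation). limma called 0 genes on this average, with 917 at an unadjusted p under 0.05, and 52 without K-ras 25 mM 72 h replicate 2. It called 1, 2, 2 and 3 genes without NIH3T3 25 mM 48 h replicate 2, NIH3T3 1 mM 48 h replicate 1 or 2, and K-ras 1 mM 72 h replicate 1.

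The glucose effect was set against itself in the 2 lines by an interaction term. limma called 0 genes at 24, 48 and 72 h, with 1464, 743 and 2220 at an unadjusted p under 0.05. For Txnip at 72 h the difference of the effects was 1.37 ± 1.52 and for Arrdc4 1.71 ± 0.77 (adjusted p = 0.749 and 0.384). At 72 h the cholesterol list had a median difference of -0.86 with 3 lower adjusted over the list alone (camera adjusted p = 0.00134, and adjusted p = 0.827 with an estimated correlation). The RAS-MAPK list had one of -1.12 with 8 lower adjusted over the list alone (camera adjusted p = 0.00134, and adjusted p = 0.816 with an estimated correlation), and the tRNA synthetase list one of -0.70 with 5 lower adjusted over the list alone (camera adjusted p = 0.00224, and adjusted p = 0.816 with an estimated correlation). Without K-ras 1 mM 72 h replicates 1 and 2 these medians were -1.47 and -0.42, -0.74 and -2.03, and -0.40 and -1.07. The cholesterol call was lost without the latter array (camera adjusted p = 0.387), and the RAS-MAPK and tRNA synthetase calls without the former (0.0648 and 0.184) or without K-ras 25 mM 72 h replicate 2 (0.0589 for both). The 72 h count was 1590 without K-ras 25 mM 72 h replicate 2, 108 without K-ras 1 mM 72 h replicate 2, 11 without NIH3T3 1 mM 72 h replicate 2 and 128 without the 6 arrays out of place. At 48 h it was 1 without NIH3T3 25 mM 48 h replicate 2. Across genes, which are not independent replicates, the log2 fold changes of the lines correlated at r = -0.13, -0.37 and -0.05 at 24, 48 and 72 h, and 0 called genes were shared. At 48 h, replicate 1 at 1 mM was out of place in both lines. The line difference thus entered the 2 glucose effects with opposite signs, which by itself makes r negative. The r at 48 h therefore does not show opposed responses to glucose.

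At 1 mM and 72 h, the lines differed in 46 genes by limma, 10 higher and 36 lower in K-ras arrays, with 2295 at an unadjusted p under 0.05. This comparison held the K-ras array with the profile of the other line. The count was 286 without it, 132 without replicate 2 of K-ras, 24 and 28 without replicates 1 and 2 of NIH3T3, and 1471 without the 6 arrays out of place. After quantile normalisation 1 gene was called, lower in K-ras arrays.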

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

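Every test in this part was chosen only after the result was seen, apart from the 2 counts of other splits of the arrays.

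The hybridisation controls bioB and bioC, which belong to no comparison, stood at 3.07 and 2.98 on the array labelled K-ras 25 mM 72 h replicate 1, far from the next highest arrays at 0.62 and 0.83. The interquartile range of that array was 0.65, against 0.45 for the next. The Gapdh 3' minus 5' difference was 2.09 on the array labelled K-ras 1 mM 72 h replicate 1, against 0.43 for the next.

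The arrays of 6 cultures had the profile of the other line, such as Il33 and Krt14 at its levels. Over 268 genes that differed at least 4-fold without overlap between the lines on 12 other arrays, the lowest share of the distance to the other line among the 6 was 0.9035, and the highest 1.01. A mixture of both lines would lie in between, and the largest distance from the other line was 0.0965 of the way, which argues against it. The bioC batch is argued against by 6 of the 28 arrays whose cluster goes against their batch, of which 5 are among the arrays out of place, and an effect of low glucose by 4 affected groups in which 1 of 2 arrays was out of place. An exchange of samples or labels between the lines remains a candidate explanation, but genotype was not analysed here, and the labels were kept. NIH3T3 1 mM 24 h replicates 1 and 2 correlated best with K-ras 1 mM 72 h replicate 2 (r = 0.85) and K-ras 25 mM 0 h replicate 2 (0.82). These partners differ in time or glucose label too. The best partner of NIH3T3 1 mM 48 h replicate 1, K-ras 1 mM 48 h replicate 2 (0.79), shared both labels. Whether glucose or time labels were also wrong was not tested.

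The line difference at 25 mM averaged over 0, 24, 48 and 72 h gave 2064 genes. Of 100 splits of the arrays within each time, 1, the real split, gave as many, and the highest of the others gave 15. This argues against chance, although 100 splits cannot show a share under 1 of 100. The line coincides with the bioC batch at 25 mM, so the splits do not separate these 2. The glucose difference averaged over both lines and 24, 48 and 72 h gave 0 genes by limma (917 at an unadjusted p under 0.05). With a real count of 0, all 100 splits give as many whatever the data, so this count says nothing about chance, and the highest of the others gave 142.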

How the results depend on the processing

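Leaving out the 6 arrays out of place, the SD filter, the bioC block the line average from 24 to 72 h and the alternatives for the lists of the interaction were chosen only after the result was seen. The causes of the changes below were not tested. Leaving out the 6 arrays chooses arrays by the profiles compared, so its line counts are not independent evidence. The replicate numbers did not pair the arrays: 23 of 91 pairs of groups correlated above 0.1, from -0.68 to 0.69. Without level or background, low signals could not be filtered and the planned dim-gene filter was not run. An array left alone in its group was assumed to vary like the others.

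Counts of called genes were 1, 0 and 2 for glucose in NIH3T3 at 24, 48 and 72 h, 0, 0 and 33 in K-ras, 0, 0 and 0 for the interaction, 2, 12, 3 and 132 for the lines at 25 mM and 0, 24, 48 and 72 h, 46 for the lines at 1 mM and 72 h, 1004 and 0 over time in NIH3T3 and K-ras, 0 for the glucose average and 2064 for the line average, all by limma. With another quantile normalisation they were 0 and 0 for NIH3T3 glucose at 24 and 72 h, 0 for K-ras glucose at 72 h, 0 to 5 for the lines at 25 mM (1, 0, 1 and 5), 1 for the lines at 1 mM, and 615 over time in NIH3T3 (341 higher and 274 lower, against 670 and 334). With the mean of all probe sets they were 0 for NIH3T3 glucose at 24 h, 6 for K-ras glucose at 72 h, 1 for the interaction at 72 h, 0, 0 and 252 for the lines at 24, 48 and 72 h, and 2 at 1 mM. With trend and robust variance they were 0 and 0 for NIH3T3 glucose at 24 and 72 h and 0, 0, 0 and 47 for the lines at 25 mM. With the compared arrays only they were 74 and 0 for NIH3T3 glucose at 24 and 72 h, 0 for K-ras glucose at 72 h, 139 for the interaction at 24 h, 0, 1028, 276 and 414 for the lines at 25 mM, 0 at 1 mM, and 4909 over time in NIH3T3. With the replicate block they were 1 and 5 for glucose at 72 h in NIH3T3 and K-ras, 0, 0, 0 and 39 for the lines at 25 mM, and 29 at 1 mM. Without the 6 arrays they were 8 and 680 for glucose at 72 h, 128 for the interaction at 72 h, 410, 1144, 998 and 1618 for the lines at 25 mM, 1471 at 1 mM, 1938 and 6 over time, and 3249 for the line average. With the SD filter they were 1 and 5 for glucose at 72 h, 1, 4 and 316 for the lines at 0, 24 and 72 h, and 4 at 1 mM. With the bioC block they were 0 for NIH3T3 glucose at 72 h, 0, 0, 0 and 1 for the lines at 25 mM, 1 at 1 mM and 0 for the line average. This block rests on the 2 NIH3T3 groups at 1 mM split between batches. In the 48 h group, the array with high bioC was out of place, at 0.9692 of the way to K-ras, against -0.0285 for its partner. The block therefore takes up part of the line difference. Calls lost and directions turned with it, here and below, do not tell the batch from the line. Without _x_at and _s_at probe sets K-ras glucose at 72 h gave 50, with centring the lines at 24 h gave 31, and with a log2 fold change of at least 1 the line average gave 828. From 24 to 72 h the line average gave 2055, or 2659 with those arrays only.

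With 1 array left out the counts ranged from 0 to 19, 0 to 2 and 0 to 2 for NIH3T3 glucose, 0 to 0, 0 to 7 and 0 to 2517 for K-ras glucose, 0 to 0, 0 to 1 and 0 to 1590 for the interaction, 0 to 2, 0 to 37, 0 to 12 and 2 to 3014 for the lines at 25 mM, 24 to 286 at 1 mM, 20 to 180 and 0 to 2552 over time, 0 to 52 for the glucose average and 961 to 2823 for the line average.

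Lists called by camera were 12 and 8 for glucose at 72 h in NIH3T3 and K-ras, 5 for the interaction at 72 h, 6 for the lines at 72 h, 15 and 12 over time, 17 for the glucose average and 5 for the line average. With an estimated correlation they were 1, 0, 0, 0, 0, 0, 0 and 0, and with fry 1, 0, 0, 1, 14, 3, 0 and 1. The interaction gave 8 after quantile normalisation, 10 with the mean of probe sets, 8 with the compared arrays only, 12 without the 6 arrays and 10 with the SD filter. The lines at 72 h gave 10 after quantile normalisation and 11 with the compared arrays only. The line average gave 3 without the 6 arrays, 3 with the SD filter, 12 with the bioC block and 8 from 24 to 72 h. With 1 array left out they ranged from 8 to 12, 3 to 14, 3 to 12, 2 to 15, 14 to 17, 8 to 16, 12 to 19 and 3 to 7.

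Medians of lists turned direction with 1 array left out. In NIH3T3 glucose at 72 h, DNA replication and S phase ran from -0.88 without the array labelled NIH3T3 1 mM 72 h replicate 1 to 1.70 without its replicate 2, mitosis from -1.75 to 1.43 and autophagy and lysosome from 0.039 to -0.36, without the same arrays. In the glucose average, DNA replication and S phase, with a median of -0.00, ran from -0.19 to 0.23 and mitosis from -0.50 to 0.024, again without these 2, and DNA replication and S phase was -0.15 without NIH3T3 25 mM 48 h replicate 1 and -0.17 with the bioC block. In K-ras glucose at 72 h, ER chaperones and unfolded protein response ran from -0.0080 without K-ras 1 mM 72 h replicate 2 to 1.80 without its replicate 1, NRF2 antioxidant genes from -0.044 to 0.97 and mitosis from 0.095 to -2.06. In the interaction at 72 h, ATF4 and amino acid response ran from -0.80 to 0.95, DNA replication and S phase from 0.69 to -1.70 and mitosis from 0.61 to -2.37, without NIH3T3 1 mM 72 h replicates 1 and 2. There ATF4 and amino acid response was also -0.33 without K-ras 25 mM 72 h replicate 2 and -0.45 without K-ras 1 mM 72 h replicate 2, and mitosis was 0.14 without the latter. With the bioC block, for the lines at 72 h ATF4 and amino acid response (0.44) and DNA replication and S phase (-0.10), turned. In the line average, hexosamine pathway (0.39), ATF4 and amino acid response (0.37), DNA replication and S phase (-0.82), mitosis (-1.08), collagens and fibrous matrix (0.25), growth arrest and FOXO targets (0.52), Idh2 (-0.087), Srxn1 (-0.021), Pola1 (-0.44), Bbc3 (0.15), Ereg (-0.29), Col11a1 (0.84), Tob1 (0.90), Per1 (0.078) and Tie1 (-0.020) did. Without _x_at and _s_at probe sets Bmf over time in NIH3T3 (-0.062) and Acsl3 (-0.099) and Epcam (0.068) in the line average turned.

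Of 236 values of named genes past the threshold, 166 stayed past it after quantile normalisation, 231 with centring, 198 with the mean of probe sets, 199 with trend and robust variance, 206 with the compared arrays only and 102 with the bioC block. With 1 array left out, 1401 of 2252 did.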

Other observations

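The tests in this part were chosen only after the result was seen.

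Arrays labelled 1 mM differed within their groups in the list ATF4 and amino acid response, genes induced when amino acids or ER function are limiting. The list score stood at 1.26 in the array labelled NIH3T3 1 mM 24 h replicate 1, at 1.39 in NIH3T3 1 mM 72 h replicate 2 and at 1.19 in K-ras 1 mM 72 h replicate 2, and at 0.38 or less in the other 9. Ddit3, a stress-induced transcription factor, stood at 4.05, 4.17 and 4.01 in these 3 arrays, and the proliferation marker Mki67 at -2.52, -2.25 and -2.39. The score of the mitosis list was -2.32, -2.82 and -2.30 in them. In the array labelled NIH3T3 25 mM 48 h replicate 1, the ATF4 and amino acid response score was 0.43 and that of mitosis -2.27. Of the 3 high arrays, NIH3T3 1 mM 24 h replicate 1 was itself out of place. It correlated best with K-ras 1 mM 72 h replicate 2 (r = 0.85), against 0.09 with its own replicate. K-ras 1 mM 72 h replicate 1, the partner of another high array, was out of place too. Whether wrong sample labels explain the difference, or the correlation below, was not tested.

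A hypothesis is that the ATF4 and amino acid response genes may be high in those cultures labelled 1 mM whose cells had left the cell cycle. Over the 12 arrays labelled 1 mM, the scores of the ATF4 and mitosis lists correlated at r = -0.9597 (permutation p = 0.00012, adjusted p = 0.0006 over 5 correlations), with rho = -0.916, and with r = -0.912 without the 2 farthest arrays. Within the 8 of them with high bioC r was -0.930 (exact permutation p = 0.00394, adjusted p = 0.00986), and over the 9 with a score under 1 it was -0.748 (adjusted p = 0.0382), or -0.424 without the 2 farthest. Over the 16 arrays labelled 25 mM it was -0.377 (permutation p = 0.156), and the difference between the glucose levels was not tested. The correlation says nothing of the order of events.

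Technical explanations of the same difference were tested as well. The score correlated with the Gapdh 3' minus 5' difference at r = -0.1281 (permutation p = 0.848), with rho = -0.0210 (permutation p = 0.959, 95% interval -0.588 to 0.560). Without the array at 2.09, K-ras 1 mM 72 h replicate 1, r was 0.171 (95% interval -0.478 to 0.699). The Actb 3' minus 5' difference gave rho = 0.210 (95% interval -0.414 to 0.700). These intervals reach from a negative relation to one above 0.5, so with 12 arrays RNA quality cannot be told apart. The means of the high and low bioC arrays differed by -0.4678 (0.149, SD 0.502, n = 8, against 0.617, SD 0.863, n = 4, exact permutation p = 0.279). Scores within each batch ranged from -0.47 to 1.19 and from -0.43 to 1.39, so the batch alone does not account for the spread. With so few arrays, a part played by the batch cannot be told apart. In NIH3T3 1 mM 72 h, the array with the high score had low bioC (-1.10) and its partner high bioC (0.28).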
